A study of Mus musculus with 16 samples.

How the data were processed

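The series measured newly made RNA in mouse embryonic stem cells, in a Control and a Mettl14 conditional knockout (CKO) genotype. Cells received 5-ethynyl uridine (EU), a uridine analogue that is built into RNA during transcription, at 0.5 mM for 10, 20, 30 or 60 min before collection, 48 h after seeding. Per the labels' protocols, labelled RNA was pulled out of Trizol-purified total RNA with a click chemistry capture kit, 0.01 µl of ERCC spike-in RNA was added to each sample before library construction, and libraries were made with the SMARTer Stranded Total RNA-Seq kit v2. The spike-in thus entered after capture, so that the ratio of mouse counts to ERCC counts carries differences in cell number, RNA recovery and capture yield together with differences in labelled RNA. Each of the 8 combinations of genotype and EU time had 2 libraries, 16 in all. The labels call the RNA both total and nascent polyA, which leaves open what RNA fraction was sequenced. They mention 8 plates and do not say that the 2 libraries of a group came from separate cultures, so the p-values measure only the spread between these samples, which may be technical.

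The deposited values are raw counts per gene identifier, not normalised, with 54446 mouse identifiers and 92 ERCC species in every library. Per the submitters' processing notes, CASAVA, Trimmomatic 0.38, HISAT2 2.1.0 and HTSeq were used with the mm10 build. The annotation release, the strand setting and the counting of exons or whole genes are not given in the sources used here, so antisense and overlapping genes, and genes with near-identical copies, have uncertain counts. The deposited files pair no identifier with a gene symbol, and the gene table supplied for this work matched 0 of the identifiers. Genes are therefore reported as groups by abundance and by response, and at most 4 by identifier. The level of Mettl14 itself, which would check the genotype labels, the 32 gene lists fixed beforehand (pathways, complexes and markers of other cell types) and settings that need gene classes were not analysed here.

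Mouse counts per library ranged from 5109162 to 28502750 and ERCC counts made up 0.6428% to 7.966% of the total. A gene-level change was tested with the quasi-likelihood F-test of edgeR 4.0.16 (R 4.3.3, robust fit, Benjamini-Hochberg adjustment over all identifiers tested, threshold 0.05), with TMM scaling of the mouse counts and edgeR's filter on low counts by group, which left 27488 identifiers holding 99.89% of the mouse counts. The overall knockout effect came from an additive model of EU time and genotype in all 16 libraries. The effect at each EU time, its change with EU time (an F-test with 3 degrees of freedom) and the change from 10 to 60 min within a genotype came from a model with 8 group means. TMM sets libraries against the bulk of their genes, so these changes are relative and not absolute. It did not centre every comparison: the median log2 fold change was 0.61 at 30 min and 0.19 over all EU times. Errors of log2 fold changes are standard errors from the F statistic.

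Output per spike-in was the mouse count divided by the ERCC count of a library. The log2 difference between genotypes was averaged over EU times, and the rate was the least squares slope of the output on EU minutes. Both were tested two-sided by exact permutation of genotype within EU time (1296 assignments, smallest possible p = 0.00154). A further measure, the slope of log2 output on log2 EU minutes, was added after the output values had been seen, and Benjamini-Hochberg values cover these 3 measures. Gene-level rates used the same slope for 9483 identifiers with an arithmetic mean of at least 10 CPM. Correlations across genes used 9284 identifiers whose mean of log2 CPM reached the log2 of 10 CPM.

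Identifiers named in the text were those with the largest positive or negative overall log2 fold change among calls with a mean log2 CPM of at least 1 and the same sign at all 4 EU times. The rule set beforehand also had parts on gene symbols, biotypes and gene lists. Those parts could not be applied without symbols, so the rule used is a reduced form, settled after the identifiers had been seen. It may name identifiers that the full rule would have left out. The comparisons, the tests and the settings named next were set before the data were examined. The other settings were DESeq2 1.42.0, its median-of-ratios size factors in edgeR, library totals, ERCC scaling, no filter and a stricter filter on low counts, the replicate number as a block, log2 EU minutes as a covariate, fits of the 4 libraries of a comparison alone, and fits without the 10 min or 60 min libraries or each library in turn. Fits without the 30 min libraries were added after the CKO 30 min libraries had been seen to stand apart, and kept 20204 identifiers after filtering, 20183 of them also tested with all libraries. Abundance classes formed without the 30 min libraries, and overlaps expected within 20 bins of abundance, were also added after the data were seen.

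The procedure was tested on simulated data with the observed library sizes and, for each gene, its mean over all libraries. No effect of EU time, no change of the knockout effect with EU time and no CKO 30 min background were simulated. Genes of low abundance were not changed. The shares below therefore need not hold for the real fits. In the overall comparison over 27488 identifiers it recovered 58.2% of genes changed 1.5-fold, 62.7% of those changed 2-fold and 86.4% of those changed 4-fold, with 5 false calls (3.5% of calls). In the 60 min comparison, with 2 libraries per group, the shares were 19.4%, 40.3% and 47%, with 6 false calls (7.79% of calls, above the threshold of 0.05). Without the 30 min libraries, over 20204 identifiers, they were 26.9%, 49.3% and 71.2% at 60 min, with 4 false calls (3.92% of calls). In the overall comparison without these libraries they were 49.3%, 61.2% and 90.9%, with 11 false calls (7.59% of calls, above the threshold of 0.05). The other single EU times were not simulated. Counting intervals are exact 95% intervals and cover counting error only, because reads without molecular identifiers are not independent molecules.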

Results

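Newly made RNA was profiled in mouse embryonic stem cells, self-renewing cultured cells derived from the early embryo, to ask how loss of Mettl14 changes transcription. METTL14 is the partner of METTL3 in the enzyme complex that methylates adenosines in messenger RNA. Control and CKO cells were labelled with EU for 10, 20, 30 or 60 min, with 2 libraries per genotype and EU time. Control libraries held 12883425 to 28502750 mouse counts. CKO libraries held 11902184 to 26557342 at 10, 20 and 60 min, but 5188643 and 5109162 at 30 min. Replicate libraries differed by more than sampling noise in all 8 groups. Across genes, the Pearson correlation of log2 CPM between replicates was 0.9689 to 0.9964 in 7 groups and 0.8235 in the CKO 30 min group.

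Captured RNA accumulated with labelling time in both genotypes, from different starting levels. In Control cells there were 11.9 ± 0.499 mouse counts per ERCC count after 10 min of EU (SD, n = 2), 45.4 ± 0.246 after 20 min, 81.8 ± 3.73 after 30 min and 132 ± 1.05 after 60 min. In CKO cells the output was 31.4 ± 4.05 after 10 min (SD, n = 2), 59.8 ± 0.668 after 20 min, 64.5 ± 24.1 after 30 min and 141 ± 19.1 after 60 min. CKO output was 2.63-fold that of Control at 10 min, a log2 difference of 1.40 (SE 0.14), and 1.32-fold at 20 min, a log2 difference of 0.40 (SE 0.01), with no overlap between the replicates of the genotypes. At 30 min the log2 difference was −0.40 (SE 0.39) and at 60 min 0.09 (SE 0.14), and the replicates of the genotypes overlapped. With 2 libraries against 2, an exact test cannot give a p below 0.333 at a single EU time.

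**Figure D1:**
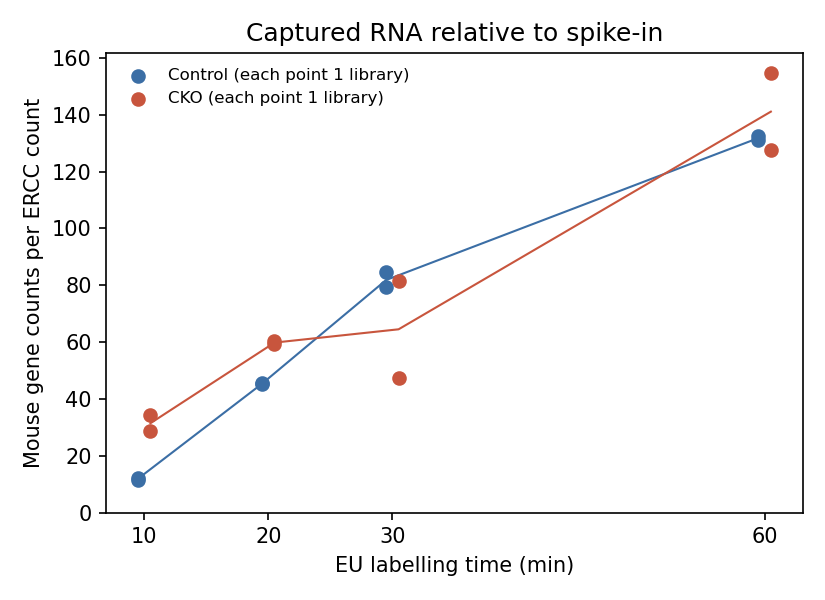
Mouse gene counts per ERCC count (y axis) against EU labelling time in min (x axis), with 1 point per library and lines through the means of 2 libraries. CKO libraries lie above Control libraries at 10 and 20 min, and the CKO 30 min libraries lie at 81.6 and 47.4.

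Averaged over the 4 EU times, CKO output per spike-in was 0.37 higher on the log2 scale (1.29-fold), which did not pass the threshold (exact permutation p = 0.157, Benjamini-Hochberg 0.236 over 3 measures). Without the 30 min libraries the difference was 0.63 (1.55-fold, exact permutation p = 0.0278, Benjamini-Hochberg 0.0834). Leaving out the second CKO 30 min library alone gave 0.47, and leaving out the first gave 0.275.

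The rate of accumulation, the quantity the labelling series was designed to compare, did not differ detectably between the genotypes when all 16 libraries were used. Output rose by 2.33 ± 0.20 mouse counts per ERCC count per min in Control (SE of the slope, n = 8) and by 2.15 ± 0.27 in CKO. The log2 ratio of the slopes was −0.12 (0.921-fold, exact permutation p = 0.694, Benjamini-Hochberg 0.694). The CKO 60 min libraries set this value: it was 0.018 without the first of them and −0.342 without the second. The absence of a detectable difference thus rests on single libraries. The ERCC species also disagreed most between these libraries, with a chi-square per degree of freedom of 122, against 3.22 to 26.9 between the replicates of the other groups. From 10 to 60 min the output grew 11.1-fold in Control and 4.49-fold in CKO. The slope of log2 output on log2 EU minutes was 1.35 ± 0.14 in Control (SE, n = 8) and 0.80 ± 0.12 in CKO, and the difference of −0.55 did not pass the threshold (exact permutation p = 0.0972, Benjamini-Hochberg 0.236).

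The same pattern held gene by gene. Of 9483 identifiers with an arithmetic mean of at least 10 CPM, 99.5% had a higher spike-in scaled level in CKO than in Control at 10 min, with a median log2 difference of 1.33 (quartiles 1.02 and 1.68). At 60 min 56% did, with a median of 0.04 (quartiles −0.15 and 0.24). Of the 9428 identifiers with a positive slope in both genotypes, 72.3% had the lower slope in CKO, with a median log2 ratio of −0.20 (quartiles −0.42 and 0.03). All these genes share the same ERCC totals and are not independent replicates. The median ratio ranged from −0.42 to −0.07 when each library was left out in turn.

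Under TMM scaling, loss of Mettl14 was accompanied by changes in both directions. Over all EU times 3152 of 27488 identifiers were called, 1861 higher and 1291 lower in CKO, and 1311 of them differed at least 2-fold (edgeR, Benjamini-Hochberg). Of the calls, 1977 had the same sign at all 4 EU times, 812 higher and 1165 lower. Of the higher calls, 991 belonged to 7305 identifiers that passed the count filter only with the 30 min libraries, and the other 20183 held 870 higher and 1291 lower calls. These 20183 were split into 5 classes by their abundance without the 30 min libraries. In the most abundant class of 4037, 201 were called higher and 790 lower, and in the least abundant class of 4037, 57 higher and 3 lower. Under ERCC scaling 99.6% of 3398 calls were higher in CKO. Fitted without the 30 min libraries, 2545 of 20204 identifiers were called, 1324 higher and 1221 lower, and 249 differed at least 2-fold. Its most abundant class of 4041 held 580 higher and 586 lower calls, and its least abundant 9 higher and 12 lower. In all, 1539 identifiers were called both with and without the 30 min libraries, all 1539 with the same sign, out of 2161 overall calls that were tested both times, and 1006 were called only without them. Leaving out either Control 30 min library lowered the overall count to 1443 or 1428, with 50% or 51.8% higher in CKO against 59% with all libraries.

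By the naming rule, 686 identifiers that rose and 1161 that fell were eligible, of which the top 2 in each direction are given. ENSMUSG00000110382.1 had 290 counts in the 8 CKO libraries, 273 of them in the CKO 30 min libraries, and 1 in the 8 Control libraries. Its depth-adjusted ratio was 372 (exact interval 66.2 to 14700), and edgeR gave a log2 fold change of 7.22 (SE 1.14, Benjamini-Hochberg adjusted p = 0.000467). ENSMUSG00000075524.3 had 258 counts in CKO, 249 of them at 30 min, and 1 in Control, a ratio of 331 (exact interval 58.9 to 13100; edgeR log2 fold change 6.86, SE 1.27, Benjamini-Hochberg adjusted p = 0.00199). Neither passed the count filter without the 30 min libraries. Their edgeR log2 fold changes ranged from 5.88 to 8.96 and from 5.29 to 8.82 when each library was left out in turn. Each of these fits kept at least 1 CKO 30 min library, so the ranges do not test a change apart from those libraries. DESeq2 gave 5.02 and 4.04, with Benjamini-Hochberg adjusted p of 0.00312 and 0.07. ENSMUSG00000072934.10 fell from 3.99 ± 0.832 CPM in Control to 1.24 ± 0.879 CPM in CKO (SD, n = 8 each), a log2 fold change of −1.80 (SE 0.46, edgeR, Benjamini-Hochberg adjusted p = 0.0168). It was −1.44 when the 30 min libraries were left out (edgeR, Benjamini-Hochberg adjusted p = 0.0137). ENSMUSG00000092540.1 fell from 4.09 ± 3.39 CPM to 1.13 ± 0.883 CPM (SD, n = 8 each), a log2 fold change of −1.72 (SE 0.49, edgeR, Benjamini-Hochberg adjusted p = 0.0289). Without the second Control 10 min library its edgeR adjusted p (Benjamini-Hochberg) was 0.0602, and without the first Control 30 min library 0.0696. For the latter 2 identifiers, the edgeR adjusted p (Benjamini-Hochberg) was 0.0973 and 0.113 with ERCC scaling and 0.0842 and 0.0582 without the 60 min libraries, and for ENSMUSG00000092540.1 it was 0.0855 without the 10 min libraries.

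At 10 min 3246 identifiers were called, 1772 higher and 1474 lower in CKO, and 1113 differed at least 2-fold (edgeR, Benjamini-Hochberg). Library totals turned the balance, with 1463 higher and 1901 lower, and ERCC scaling gave 11834 higher and 128 lower. The most abundant class of 4037 held 798 higher and 773 lower calls. The fit that left out the 30 min libraries called 4601, 2197 higher and 2404 lower. Leaving out the first or second CKO 30 min library alone raised the 10 min count to 5256 or 5241, whereas a fit of the 4 libraries of this comparison alone called 1680.

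At 20 min 264 identifiers were called, 194 higher and 70 lower in CKO (edgeR, Benjamini-Hochberg). The most abundant class held 134 higher and 59 lower calls, and 50 calls differed at least 2-fold. With the 30 min libraries left out, 384 were called, 250 higher and 134 lower. The count fell to 86 or 77 without the first or second Control 20 min library and to 90 without either CKO 20 min library, and rose to 678 or 681 without the first or second CKO 30 min library. A fit of the 4 libraries of this comparison alone called 2353, 1266 higher and 1087 lower, which is more than the same kind of fit at 10 or 60 min, and DESeq2 called 827, 486 higher and 341 lower.

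At 30 min the libraries differed across the whole range of abundance. Of 27488 identifiers, 13339 were called, 8076 higher and 5263 lower in CKO (edgeR, Benjamini-Hochberg). Of these, 4853 higher and 1 lower belonged to the 7305 identifiers that passed the count filter only with the 30 min libraries, which fixes their direction. The other 20183 held 3223 higher and 5262 lower calls. In the classes formed without the 30 min libraries, the median log2 fold change was 2.07 in the least abundant class, 1.04, 0.16 and −0.33 in the classes above it, and −0.61 in the most abundant class, where 3135 identifiers were lower and 104 higher. At 10, 20 and 60 min the medians of the same classes lay between −0.04 and 0.10. The CKO 30 min libraries detected 30583 and 31826 identifiers, against at most 26857 in any other library, from the fewest counts. Identifiers without a count in any Control library, 19033 in number, took 1.674% and 1.629% of their counts, against at most 0.01395% in the other CKO libraries. The balance of directions turned without the first Control 30 min library, with 2898 higher and 4039 lower of 6937, without the second, with 2703 higher and 3747 lower of 6450, and under the stricter count filter, with 2532 higher and 2652 lower.

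**Figure D2:**
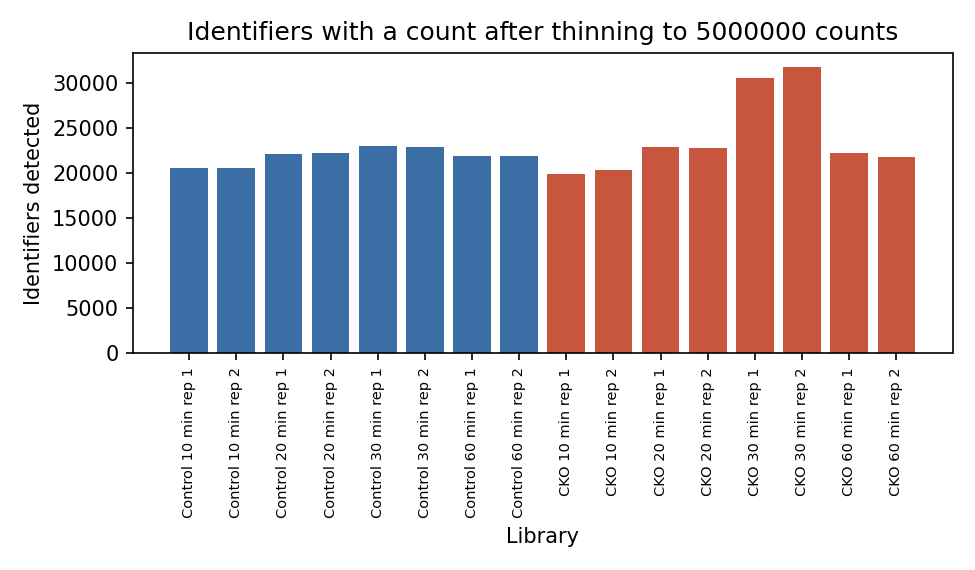
Identifiers with at least 1 count (y axis), in each of the 16 libraries (x axis) after random thinning to 5000000 mouse counts. Bars are single libraries, blue for Control and red for CKO, and the CKO 30 min libraries reach 30537 and 31780, with at most 23001 in the others.

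At 60 min 723 identifiers were called, 492 higher and 231 lower in CKO, and 87 differed at least 2-fold (edgeR, Benjamini-Hochberg). The most abundant class held 351 higher and 188 lower calls. Without the 30 min libraries 997 were called, 614 higher and 383 lower. The count fell to 144 or 157 without the first or second Control 60 min library and to 201 without the first CKO 60 min library, and rose to 1714 or 1709 without the first or second CKO 30 min library, with 50.1% or 49.9% higher in CKO against 68% with all libraries. A fit of the 4 libraries of this comparison alone called 1744, 955 higher and 789 lower, and DESeq2 called 1875, 892 higher and 983 lower.

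**Figure D3:**
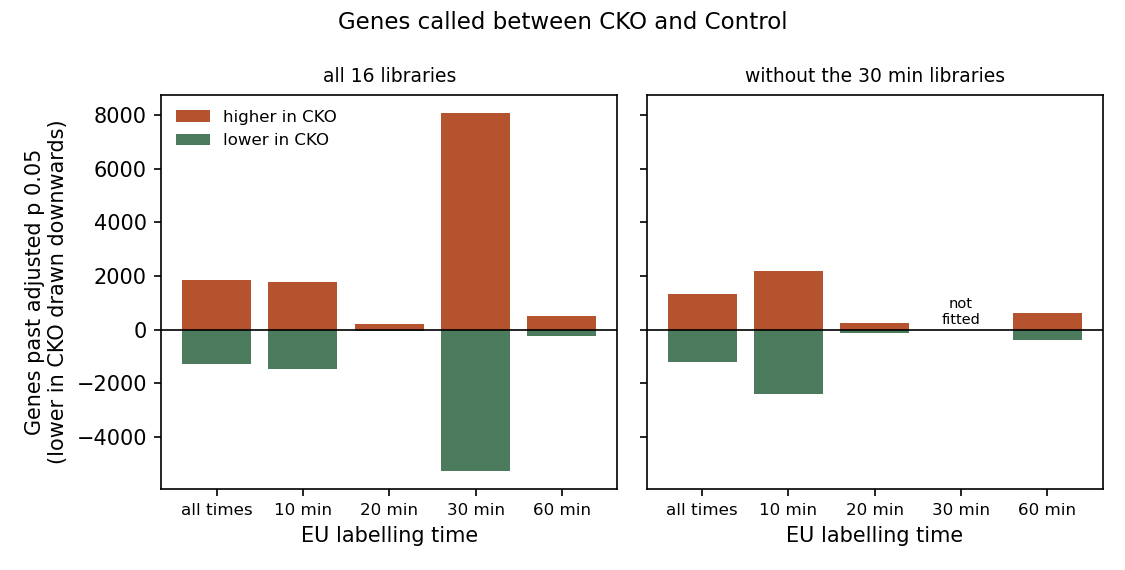
Number of identifiers past an edgeR adjusted p of 0.05 (y axis, higher in CKO upwards and lower in CKO downwards) over all EU times and at each EU time (x axis), with all 16 libraries on the left and without the 30 min libraries on the right. The 30 min bar reaches 8076 upwards and 5263 downwards, and the 20 min bars are the smallest in both panels.

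The difference between CKO and Control varied across the EU times for part of the genes. If the libraries of a group came from the same culture, labelling time cannot be told apart from differences between cultures or captures. The test of genotype by EU time called 6238 identifiers with all libraries and 1127 of 20204 without the 30 min libraries (edgeR, Benjamini-Hochberg). The count was 4097 or 3972 without the first or second Control 30 min library.

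Captured RNA also changed its make-up between 10 and 60 min of labelling, and largely in the same direction in both genotypes. From 10 to 60 min of EU, 1892 identifiers rose and 882 fell in Control, and 2462 rose and 1714 fell in CKO (edgeR, Benjamini-Hochberg). With ERCC scaling nearly all changes were rises, with 18273 rising and 1 falling in Control and 14539 rising and 17 falling in CKO. Under TMM, rises shared by both genotypes numbered 1190, where lists independent within 20 bins of abundance would share 501, and shared falls numbered 512, against 114. Opposite calls numbered 31. Of the identifiers that rose in Control, 92.1% had a positive log2 fold change in CKO, with a median of 0.76 in Control and 0.61 in CKO. Of those that fell, 88.1% had a negative one in CKO, with medians of −0.90 and −0.75. At 30 min the identifiers that rose in Control had median log2 changes from 10 min of 0.50 and 0.51 in the Control libraries. In the CKO libraries these were −0.25 and −0.27. Those that fell in Control had −0.46 in both Control libraries at 30 min, and −0.65 and −0.71 in the CKO libraries. Across 9284 identifiers with a mean log2 value of at least 10 CPM, the fold changes of the genotypes correlated with Pearson r = 0.651 (Spearman rho = 0.612), genes not being independent replicates. Across all 27488 identifiers, which include the 7305 that passed the count filter only with the 30 min libraries, the correlation was 0.144 (Spearman rho = 0.251). Without the 30 min libraries 2150 rose and 1746 fell in Control, and 2971 rose and 2429 fell in CKO. The Control count was 1389 or 1431 without the first or second Control 60 min library and 4542 or 4558 without the first or second CKO 30 min library.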

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

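The tests of depth, of counting strand, of few starting molecules and of the spike-in amount were chosen after the results were seen, as were the fits without the 30 min libraries.

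The test of genotype by EU time called 6238 identifiers (edgeR, Benjamini-Hochberg), and 1127 without the 30 min libraries, which singled this result out as a difference between time points. Counts on identifiers that no Control library detected singled out the CKO 30 min libraries, with 1.674% and 1.629% of their counts on such identifiers.

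Both CKO 30 min libraries detected more identifiers, from fewer counts, than any other library. Lower depth is argued against by that detection itself, since fewer counts detect fewer identifiers. After thinning to 5000000 counts the lower of them detected 30537, against at most 23001 in the others. They were already near that depth and thinning can only lower detection in the deeper libraries, so this outcome was fixed in advance. Counting on the opposite strand is argued against by identifiers above 300 CPM in Control, whose median log2 ratio was −0.44. RNA of another cell type stays open. The top 1% of Control-silent identifiers held at most 19.6% of their counts, under the bound of 25% set beforehand against it. This share leaves out genes that another cell type has in common with stem cells, and no marker list was run, so it cannot decide. Reads spread over the genome, such as DNA, stay open, since 34.1% of the Control-silent identifiers had a count, between the bounds of 25% and 50% set beforehand. Few starting molecules amplified many times may contribute, with a median of 13 and 14 counts per detected Control-silent identifier against 1 to 3 in the other CKO libraries, and a biological change at this EU time stays untested. Both CKO 30 min libraries detected 2074 Control-silent identifiers, against 962 if independent. Over the 6492 detected in either, their counts had a Spearman rho of −0.209. That expectation takes all identifiers as equally detectable, so the overlap does not decide between these explanations.

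CKO cells had 2.63-fold the Control output per spike-in at 10 min and 1.07-fold at 60 min. Less spike-in RNA in the CKO 10 min libraries cannot account for the 3246 identifiers that changed their share of the library at that time, but it could account for the output itself and cannot be told apart from more labelled RNA. The difference could also lie in the Control 10 min libraries, through more spike-in RNA or a lower capture yield, which was not tested. From 10 to 20 min the output rose 3.81-fold in Control and 1.9-fold in CKO, and from 20 to 60 min 2.91-fold and 2.36-fold. More of the RNA that accumulates with labelling time would make the 10 min change resemble the 60 against 20 min change in Control. The Spearman rho across 9284 identifiers was −0.002, with −0.034 to 0.028 over 16 combinations of single libraries. That lies under the 0.2 set beforehand for this explanation but not wholly at or under the bound of 0 set against it, so it stays undecided. A comparison added afterwards, the 20 against 10 min change with the 60 against 30 min change in Control, gave 0.153, and 0.113 to 0.131 over single libraries, but uses another later contrast than the test. These values within Control also lay under 0.2, so a rho under that bound cannot by itself speak against the explanation. For the CKO against Control change at 20 min, where CKO output was also higher, the rho with the 60 against 30 min change in Control was 0.134.

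The real assignment of these libraries to genotypes within EU time called more identifiers than the other splits drawn. Most other splits put the libraries of at least 1 group on opposite sides, which widens the spread within each side. They therefore cannot exclude a chance difference between cultures. The protocol mentions 8 plates, and if both libraries of a group came from 1 culture the splits measure technical spread only. The real split called 3152 identifiers and was the only 1 of 100 splits of the 16 libraries to call as many, with 461 the highest of the others. Without the 30 min libraries the real split called 2545, again the only 1 of 100, with 10 the highest of the others.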

How the results depend on the processing

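The median over ERCC species, the output without the most abundant identifiers and all fits without the 30 min libraries were chosen after seeing the data. Except where a cause is given, the cause of a change was not tested. The count over all EU times stayed within 1.5 times 3152 under all 12 other settings run. Its share higher in CKO moved from 59% to 73% with log2 EU minutes as a covariate (1584 higher, 587 lower) and to 51.3% with the stricter filter. Without the 2 CKO 30 min libraries alone the share was 50.2% (1426 higher, 1417 lower). With ERCC scaling, under which the median log2 fold change was 1.14 at 10 min, 0.36 at 20 min, 0.53 at 30 min, 0 at 60 min and 0.60 over all EU times, 11962 were called at 10 min (98.9% higher in CKO), 146 at 20 min, 12 at 60 min, 10546 for the change with EU time, 18274 for 60 against 10 min in Control and 14556 in CKO, and 99.6% of the calls over all EU times were higher. DESeq2 called 4895 at 10 min, 827 at 20 min, 1875 at 60 min and 4320 in Control. Fits of 4 libraries alone called 1680 at 10 min, 2353 at 20 min, 1744 at 60 min and 2632 in CKO. The stricter filter tested 13525 identifiers and called 5184 at 30 min and 3633 for the change with EU time, which was 1127 without the 30 min libraries. The share of calls higher in CKO moved from 54.6% to 43.5% at 10 min and from 68% to 50.1% at 60 min with library totals (54.8% with median-of-ratios factors), and from 60.5% to 75.5% and 73.9% at 30 min, where the stricter filter gave 48.8%; the share rising in Control moved from 68.2% to 54.9% with library totals. At 20 min it was 73.5%, and 100% with ERCC scaling.

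Replicate numbers did not pair the samples: the correlations of deviations over 28 pairs of groups lay between −0.0166 and 0.00851. With the replicate block 2486 were called over all EU times and 403 at 20 min, and no other count moved by over 1.5 times. Output per spike-in was 0.629 without the 30 min libraries. The rate ratio was 0.004 with the median over ERCC species, and leaving out the 30 min libraries cannot move it, since 30 min is the mean EU time. Leaving out each library in turn, with the lone sample assumed to vary like the other groups, gave 1428 to 2956 calls over all EU times, 2263 to 5256 at 10 min, 77 to 681 at 20 min, 6450 to 14292 at 30 min, 144 to 1714 at 60 min, 3972 to 8411 for the change with EU time, 1389 to 4558 in Control and 2848 to 5906 in CKO. Output then ranged from 0.275 to 0.47 and the rate ratio from −0.342 to 0.018. Settings that need gene classes or gene lists were not run.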

Other observations

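Chosen after the data were seen, the comparison of the knockout effect between EU times used no library on both sides. The knockout effects at different EU times were partly shared. Across 9284 identifiers with a mean log2 value of at least 10 CPM, the log2 fold changes at 10 and 20 min correlated with Pearson r = 0.51 (Spearman rho = 0.47), those at 20 and 60 min with 0.50 (0.46) and those at 10 and 60 min with 0.45 (0.41), genes not being independent replicates. Of the 264 identifiers called at 20 min, 242 (91.7%) had the same sign at 60 min and 161 were also called there in the same direction, against 19.4 for lists independent within 20 bins of abundance, and 8 were called in the opposite direction, against 15.5. Of the 3246 called at 10 min, 2458 (75.7%) had the same sign at 60 min, and 386 were called there in the same direction against 136, with 32 called in the opposite direction, against 134. The test of genotype by EU time without the 30 min libraries still called 1127 of 20204 identifiers as differing among these times (edgeR, Benjamini-Hochberg).

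The 30 min effect correlated with the 10 min effect with Pearson r = 0.19 (Spearman rho = 0.18), with the 20 min effect with 0.29 (0.24) and with the 60 min effect with 0.40 (0.41). Between 10 and 30 min, 1180 identifiers were called in the same direction, against 944 for such lists, and 764 in opposite directions, against 1030. Between 20 and 30 min 129 were called in the same direction, against 62.5, and 55 in opposite directions, against 129. Between 30 and 60 min 347 were called in the same direction, against 193, and 158 in opposite directions, against 339. Of the calls at 10 min, 56.5% had the same sign at 30 min. Of the 13339 calls at 30 min, 49.6% had the same sign at 60 min, and 58.4% after leaving out 2035 with no change value there.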
